A study of Homo sapiens with 6 samples.

How the data were processed

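Expression was measured in 6 RNA samples of the RD cell line, 3 infected with control vector and 3 with the MyoD-E construct, each on 1 array. Per the labels' protocols, cells were grown in 10% calf serum, infected, selected for 48 h with puromycin at 1 ug/mL and differentiated for 24 h, and biotin-labelled RNA was made from 8 ug of total RNA. The deposited values are log2 expression levels per probe set, and the submitters' processing notes name RMA and the affy package without versions. RMA corrects background, normalizes arrays to a common distribution by quantiles and summarises probes, so a change in total RNA per cell is not visible in such values. Any further filter is not given in the sources used here, and the table has 54675 probe sets with no missing value. Groups and replicate numbers came from the labels.

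All 62 control probe sets were left out of the tests, which leaves 54613. In the platform's annotation table, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 were not named here. Gene IDs of 41037 of the first kind matched a RefSeq gene table (GRCh38 assembly, used for names only), and 54 kept the symbol of the annotation. No gene was named from a probe set with several, so RUNX1 is not analysed here. A gene was represented by 1 probe set, the one with the highest mean over all 6 arrays, which gave 19775 genes. Probe sets whose IDs end in _x_at or _s_at can be shared between genes or transcripts and are called shared in the text.

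Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, two-sided), as MyoD-E minus control vector. P-values were adjusted by Benjamini-Hochberg over all 54613 probe sets and called under 0.05. The standard errors printed are limma's moderated ones. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 26 lists, and again with the correlation estimated from the data. The second form also rests on the 4 residual degrees of freedom of the arrays, far fewer than with a preset correlation. Its larger p-values are therefore not due to correlation alone. For the list of published MyoD factors, camera p rose from 0.0793 to 0.145 although the estimated correlation was -0.0701. Lists, tests, most alternatives and the rule for named genes were chosen before the data were examined. MYLPF and NDUFA4 are listed under current symbols MYL11 and COXFA4. That match was added after values had been seen, and the lists were also tested without it.

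The rule named the 12 largest increases and 12 largest decreases among genes called with at least a 2-fold change whose groups did not overlap, up to 3 called members of each list in each direction, and a fixed set of genes whatever their values. It gave 152 genes. The text gives all of the largest increases and decreases, the measured genes of the fixed set, and examples from the lists that were picked among the 152 after their values were seen.

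The fits were tested on simulated data with the spread of these arrays before use. Of 50 probe sets changed by each fold in a fit of 54613, 3 were recovered at a fold of 1.25, 28 at 1.5, 45 at 2 and 49 at 4, with 0 unchanged probe sets called. Far fewer probe sets were changed there than the 15011 called in the data. That makes the adjustment stricter in the simulation, so these shares do not give the sensitivity of the real fit. A simulation with no change called 0 probe sets. For 19775 simulated genes camera found the 1 list that was changed and called 0 of 25 others. The simulated probe sets were drawn independently of each other, so this cannot show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation reached 0.28, in the respiratory chain list. Alternatives covered each array left out, the replicate number as a block, dim probe sets, other scalings between arrays, the variance model, array weights, the probe set per gene, the correlation between genes and a test against a fold of 1.5.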

Results

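RD cells, an established line from an embryonal rhabdomyosarcoma (a childhood tumour of cells related to skeletal muscle precursors), were infected with 1 of 2 retroviruses. One carried a construct for a heterodimer of the myogenic factor MyoD and an E protein, called MyoD-E here, and the other was an empty control vector. After 48 h of selection in puromycin at 1 ug/mL the cells were kept for 24 h in medium with 1% horse serum, insulin and transferrin, a low-serum medium that favours muscle differentiation. Total RNA was then measured on oligonucleotide arrays, with 3 arrays per group and 54613 probe sets tested on each. The values are log2 expression levels, so a difference of 1 is a factor of 2. Array medians lay between 5.90 and 5.94, and the number of arrays limits the precision. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

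The comparison of MyoD-E with control vector asks how expression in these tumour cells differs when the MyoD heterodimer is supplied. Genes of the contractile apparatus had the largest measured increases. MYH8, the perinatal myosin heavy chain, went from 5.30 ± 0.46 to 13.53 ± 0.11 (SD, n = 3 in each group), a 300.8-fold increase. TNNC1, the slow and cardiac troponin C, rose 94.2-fold, MYH2, a fast adult myosin heavy chain, 87.5-fold, and MYOZ2, a Z-disc protein, 85.6-fold. The control level of MYH2, 3.86, lay below the lower quartile of each array (4.32 to 4.37), and those of MYH8 and TNNC1 lay below the array medians, so these are measured ratios over a dim level and their order is not firm. The strongest decrease was that of IGFBP5, a secreted binding protein for insulin-like growth factors, which went from 11.92 ± 0.47 to 6.98 ± 0.85 (SD, n = 3), a log2 change of -4.94.

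In limma with Benjamini-Hochberg adjustment, 6608 of 19775 genes passed an adjusted p of 0.05, 2769 of them higher and 3839 lower with MyoD-E. At least a 2-fold change was seen for 703 called genes upward and 278 downward, and at least a 4-fold change for 207 upward and 23 downward. With arrays centred on the median of the housekeeping genes, the 2-fold counts turned round, to 491 upward and 654 downward (probe sets, 980 and 1341). In each other setting where they were counted, more genes and more probe sets rose than fell by 2-fold. Of the probe sets, 6248 were higher and 8763 lower. The split between higher and lower genes depended on the scaling between arrays: it was 4801 to 2489 when arrays were centred on the mean of 13 housekeeping genes and 1387 to 6851 when they were centred on the median of those genes, which shifted every log2 fold change by 0.13 and -0.23. With arrays centred on the poly-A spike-in controls the split was 2552 to 3161. The median version does not follow the changes of its own genes. The median level over the 13 genes rose from 11.94 to 12.17, while their median log2 fold change was -0.0863. After that centring 6 of the 13 were called lower and 0 higher, against 3 and 0 before it.

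**Figure D1:**
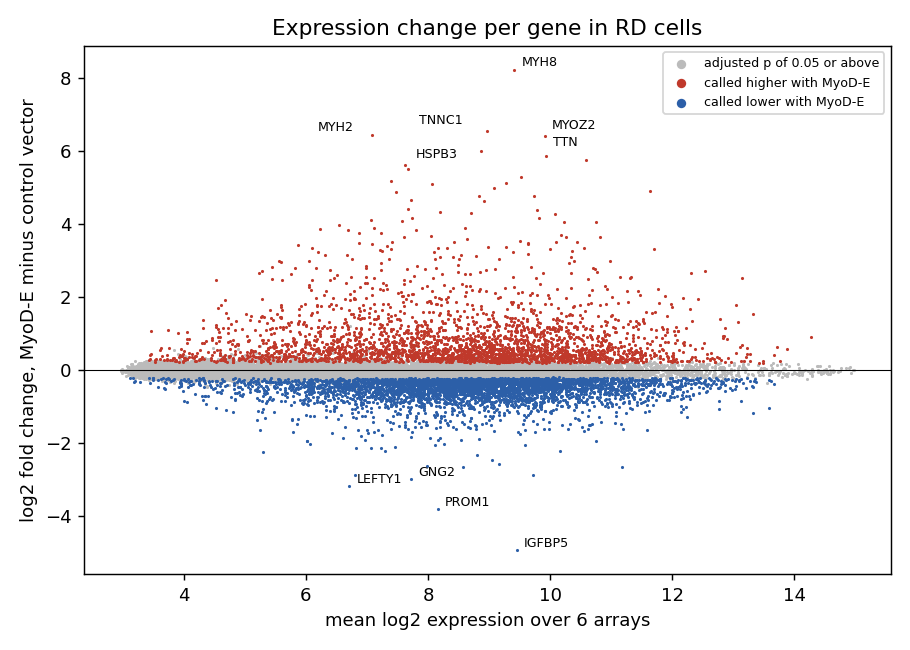
Log2 fold change (MyoD-E minus control vector) of each of 19775 genes against its mean log2 expression over 6 arrays. Red points are the 2769 genes called higher, blue points the 3839 called lower and grey points the others. The named points are 6 of the largest increases, up to 8.23 for MYH8, and 4 of the largest decreases, down to -4.94 for IGFBP5.

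Correlation over all probe sets was 0.996 to 0.997 between arrays of a group and 0.978 to 0.981 between groups. The first principal component, with 82.9% of the variance, separated the groups.

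The other increases among the 12 largest were also mostly muscle genes. HSPB3, a small heat shock protein of muscle, rose by 6.01 ± 0.23 (log2 fold change ± SE), TTN, the giant sarcomeric protein titin, by 5.89 ± 0.11, and CKM, muscle creatine kinase, by 5.78 ± 0.09. PVALB, the calcium buffer parvalbumin, rose by 5.62, MYH3, the embryonic myosin heavy chain, by 5.30, LDB3, a Z-disc protein, by 5.20, and UNC45B, a myosin chaperone, by 5.14. LINC03013, a long non-coding RNA, rose by 5.53. The control levels of HSPB3, PVALB, LDB3 and LINC03013 (5.85, 4.81, 4.80 and 4.90) lay below the array medians. Their changes are thus also measured over a dim level, and their order is not firm. Of the 5 other probe sets of TTN, 3 were also called higher and 1 lower.

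Of the 46 measured sarcomere genes, 37 rose, none fell and 9 did not pass, the same numbers when adjusted over the list alone. Their median log2 fold change was 2.47, and the list was higher in limma's camera (adjusted p = 5.541e-32 over 26 lists). The adjusted p was 0.0542 with an estimated correlation between genes, and 0.0477 when a gene found only under an updated symbol was left out. Genes of excitation-contraction coupling moved the same way, with 22 of 26 higher and none lower (median 1.36, camera adjusted p = 4.098e-16, adjusted p = 0.0696 with an estimated correlation). CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, rose by 4.18 ± 0.22 and SRL, sarcalumenin, by 3.05 ± 0.07. CACNA2D1, a calcium channel subunit, rose by 2.76.

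In the muscle metabolism list, which holds muscle enzymes but also the ubiquitin ligases FBXO32 and TRIM63 and the growth inhibitor MSTN, 16 of 20 genes rose and 2 fell (median 1.04, camera adjusted p = 6.471e-10, adjusted p = 0.0675 with an estimated correlation). After CKM, the largest rises were those of FBXO32 by 4.63 and PGAM2, the muscle phosphoglycerate mutase, by 4.43. MSTN, which encodes myostatin, fell by 0.57. PHKA1, a muscle phosphorylase kinase subunit, fell by 0.24, a call that ended with arrays centred on the spike-ins or on the housekeeping mean and in 4 of the 6 fits without 1 array. The general respiratory chain and glycolysis lists were not called (adjusted p = 0.0624 and 0.808). Of 34 respiratory chain genes, 5 were higher and 1 lower. The 5 became 1 without control vector replicate 1, without MyoD-E replicate 1 or with spike-in centring, 2 without MyoD-E replicate 2, and 3 without each other array, and housekeeping centring gave 16 (mean) and 0 (median). This list passed without control vector replicate 2 (adjusted p = 0.0316), with an intensity trend (0.0148), with all probe sets of a gene averaged (0.0468) and with the housekeeping mean (0.0121). Of 22 glycolysis genes, 5 were higher and 4 lower, against 7 and 1 with the housekeeping mean and 1 and 8 with its median.

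Fusion and adhesion genes rose in 11 of 17 cases and fell in 2 (median 0.75, camera adjusted p = 8.315e-06, adjusted p = 0.0747 with an estimated correlation). DYSF, the membrane repair protein dysferlin, rose by 3.53 ± 0.19, CAV3, muscle caveolin, by 3.25 ± 0.10 and CD9, a tetraspanin, by 2.05 ± 0.18. Neither of the 2 other probe sets of CD9 was called. KIRREL1, a cell adhesion protein, fell by 1.22. DMD, dystrophin, fell by 0.81 and on another shared probe set fell by 0.57, while a dim unshared one, at 4.15 in controls, gave -0.42 (limma adjusted p = 0.0638).

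**Figure D2:**
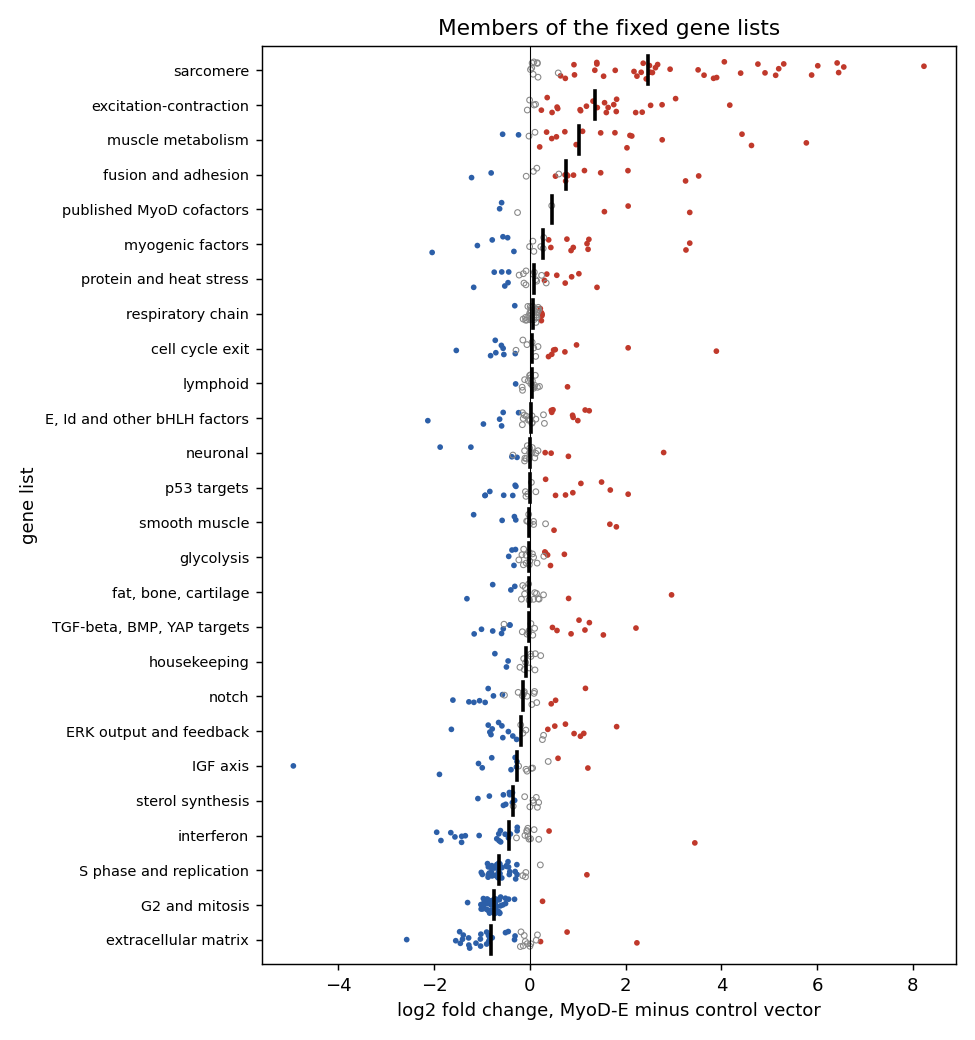
Log2 fold change (MyoD-E minus control vector, horizontal axis) of each measured member of 26 gene lists (vertical axis, ordered by median). Filled points are called genes, red higher and blue lower, open points are not called and the black bar is the list's median. The sarcomere median is 2.47 and the extracellular matrix median -0.81.

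Myogenic factors moved both ways. MEF2C, a transcription factor that acts with MyoD, rose by 3.34 ± 0.09, SMYD1, a muscle methyltransferase, by 3.26 and MEF2D by 1.23. MYOG, myogenin, rose by 1.20 ± 0.11. PAX7 and PAX3, factors of muscle precursors, fell by 2.04 and 1.09, and PITX3 fell by 0.78. Of 22 measured members, 10 were higher and 6 lower. The list was called higher (median 0.28, camera adjusted p = 0.0131), with an adjusted p of 0.364 with an estimated correlation, 0.18 without probe sets shared between transcripts or genes and 0.115 with arrays centred on the housekeeping mean.

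MYOD1 read 11.02 ± 0.07 in control cells and 11.46 ± 0.13 with MyoD-E (SD, n = 3 each), a log2 difference of 0.44 (limma adjusted p = 0.00372) that became 0.21 (adjusted p = 0.201) with arrays centred on the housekeeping median. That centring also raised its standard error from 0.084 to 0.141. The labels do not give the sequence of the construct, so the MYOD1 and TCF3 probe sets may not read it. MYF5 stayed near the lower end of the range at 3.91 in both groups. MYF6 was at 4.81 and 5.10 (limma adjusted p = 0.17), which became a log2 difference of 0.47 (adjusted p = 0.00548) without MyoD-E replicate 2.

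Among E proteins and their competitors, TCF3, which encodes E2A, read 0.59 lower. Of its 13 other probe sets 6, all shared, were also called lower and 1 dim one was called higher, and the brightest unshared probe set gave -0.11 (limma adjusted p = 0.572). TCF4 fell by 0.56. TCF12 fell by 0.23, a call that ended with arrays centred on the spike-ins or the housekeeping mean and in 4 of the 6 fits without 1 array. MSC, the MyoD competitor musculin, fell by 0.63 ± 0.10. The Id proteins, which bind E proteins, moved apart: ID1 rose by 1.24 ± 0.10 and ID2 by 0.89 ± 0.18, while ID3 fell by 0.97 ± 0.13. BHLHE40, a circadian repressor, fell by 2.13, and SNAI1 rose by 1.16. TWIST1 was at 3.57 and 3.61. The whole list of 28 basic helix-loop-helix and related factors, with 8 higher and 6 lower (5 and 10 with the housekeeping median), was not called (camera adjusted p = 0.468). Factors known from published work on MyoD in this tumour type include MEF2C, CDKN1A and ZBTB18, which rose by 3.34, 2.05 and 1.56. That list was partly chosen by the study, so its 3 higher and 2 lower of 7 members are not independent evidence, and it was not called (camera adjusted p = 0.159), except with arrays centred on the housekeeping median (0.000115).

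**Figure D3:**
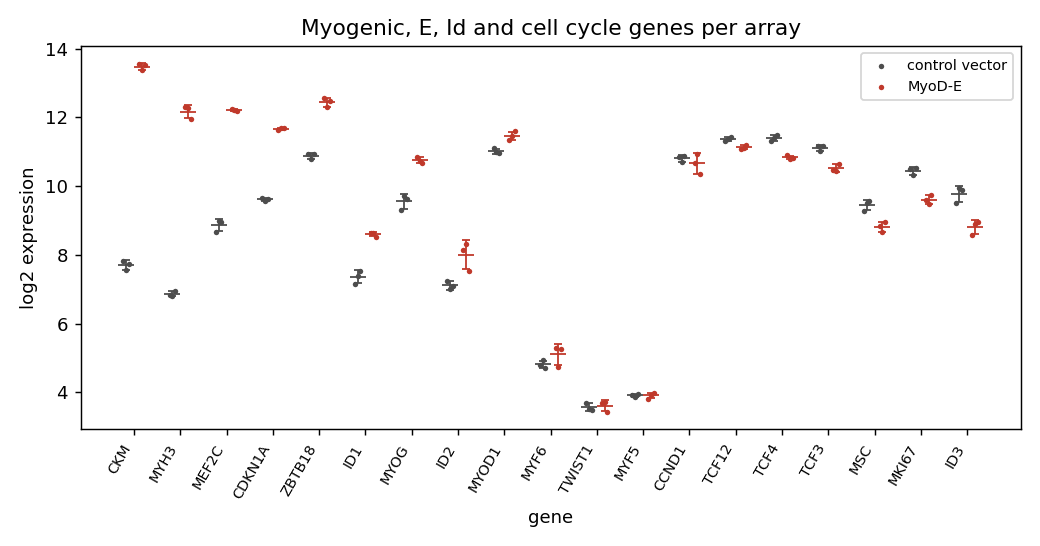
Log2 expression of 19 genes chosen before the data were examined, per array, in control vector (grey) and MyoD-E (red) cells. Points are arrays, the horizontal bar is the mean of 3 and the error bar 1 SD. CKM went from 7.70 to 13.48, while MYF5 was at 3.91 in both groups.

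Cell cycle genes fell together by smaller amounts. Of 40 genes of G2 and mitosis, 39 fell (median -0.74, camera adjusted p = 1.103e-19, adjusted p = 0.0696 with an estimated correlation). TOP2A, topoisomerase II alpha, fell by 1.02, NEK2, a mitotic kinase, by 1.02 and MKI67, the proliferation antigen Ki-67, by 0.84. CDC25C fell by 1.30 and 1.31 on 2 shared probe sets and read -0.23 (limma adjusted p = 0.112) on a dim unshared one, at 5.30 in controls. The exception was CDC25B, a phosphatase that activates cyclin-dependent kinases, which rose by 0.27, a call that ended with arrays centred on the spike-ins or the housekeeping median, and without control vector replicate 2 or MyoD-E replicate 1. Of 41 replication genes, 36 fell and 1 rose, or 2 rose without MyoD-E replicate 3 (median -0.65, camera adjusted p = 1.2e-13, adjusted p = 0.0696 with an estimated correlation). PRIM1, a DNA primase subunit, fell by 1.01, GINS4 by 0.99 and MCM5, of the replicative helicase, by 0.88, while E2F8, a repressor of the E2F family, rose by 1.19 ± 0.11.

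Genes of cell cycle exit were not called against other genes (camera adjusted p = 0.468), with 8 of 23 higher and 8 lower, and 4 higher with the housekeeping median. CDKN1C, the inhibitor p57, rose by 3.90 ± 0.09, CDKN1A, the inhibitor p21, by 2.05 ± 0.07 and GADD45G by 0.98. CDKN2A fell by 0.72 and RBL1 by 0.82. MYCN was called lower on 2 shared probe sets, with log2 changes of -1.54 and -0.42, and the brightest unshared one, at 6.14 in controls, gave 0.05. CCND1, cyclin D1, was at 10.81 and 10.66 (limma adjusted p = 0.507) and read -0.37 (adjusted p = 0.026) with arrays centred on the housekeeping median. Targets of p53 were not called (camera adjusted p = 0.339), with ZMAT3 higher by 1.68 and log2 changes of -0.94 for DDB2 and -0.93 for TNFRSF10B.

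Extracellular matrix genes fell in 23 of 36 cases and rose in 3 (median -0.81, camera adjusted p = 1.291e-06, adjusted p = 0.0747 with an estimated correlation). MMP2, a gelatinase, fell by 2.57 ± 0.11, FBN1, fibrillin-1, by 1.55 and S100A4 by 1.47. Neither of the 2 other probe sets of MMP2 was called. COL12A1, a fibril-associated collagen, rose by 2.24 ± 0.24. COL1A2 rose by 0.78 on each of 2 shared probe sets and read -0.06 on an unshared one. SPARC read 0.22 higher, a call lost in 5 of the 6 fits without 1 array, with median centring and with spike-in centring, and -0.003 with the housekeeping median, while its unshared probe set rose by 1.06.

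Interferon response genes fell in 18 of 30 cases and rose in 2 (median -0.43, camera adjusted p = 0.000373, adjusted p = 0.347 with an estimated correlation). IFIH1, a sensor of viral RNA, fell by 1.94, RSAD2, an antiviral enzyme, by 1.86 and IFIT2 by 1.65. USP18, a protease that removes ISG15 and restrains interferon signalling, rose by 3.45 ± 0.11, and IRF7 by 0.40, a call that ended without control vector replicate 2 and with the housekeeping median. Sterol synthesis genes fell in 10 of 18 cases and rose in 0, against 8 lower and 5 higher with the housekeeping mean (median -0.35, camera adjusted p = 0.0332, adjusted p = 0.525 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell by 1.08 and HMGCS1 by 0.84. This list's call ended without dim probe sets (adjusted p = 0.134), without control vector replicate 3 (0.0678) and with arrays centred on the housekeeping median (0.0523).

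Notch, insulin-like growth factor, ERK output and TGF-beta lists were not called (camera adjusted p = 0.169, 0.0843, 0.468 and 0.404). Notch members were lower in 8 of 22 cases and higher in 3 (14 and 1 with the housekeeping median), with log2 changes of -1.61 for NOTCH3, -1.27 for HEY1, -1.17 for NRARP and 1.16 for DLL1. RBPJ rose by 0.54 and 0.38 on 2 shared probe sets and read -0.13 on a dim unshared one. The Notch list passed without MyoD-E replicate 3 (adjusted p = 0.034) and under both housekeeping centrings (0.0444 and 0.0171). In the insulin-like growth factor list 9 of 17 were lower and 2 higher, with log2 changes of -1.89 for IGFBP6, -1.07 for IGFBP2 and 1.21 for IGFBP3, and it passed without shared probe sets (0.0104) and under both housekeeping centrings (0.0245 and 0.000248). Of 23 ERK output genes 11 were lower and 7 higher, with log2 changes of 1.81 for FOSL1 and -1.64 for HMGA2. Of 23 TGF-beta, BMP and YAP targets 8 were higher and 7 lower, with log2 changes of 2.22 for TGFB3 and -1.16 for SKIL. The 1 other probe set of TGFB3 was not called. Camera compares a list with other genes. In fry, which asks whether a list's genes moved one way on balance, the adjusted p was 0.000278 for cell cycle exit (up), 6.287e-05 for p53 targets (up, with a median of -0.00567), 0.0162 for Notch (down) and 0.00323 for the insulin-like growth factor list (down). It was 0.0391 for ERK output (down), 0.00523 for TGF-beta targets (up, with a median of -0.0207), 0.00288 for housekeeping genes (down) and 1.748e-05 for the published factors (up).

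The remaining decreases among the 12 largest were a mixed group. PROM1, the progenitor surface marker CD133, fell by 3.81 ± 0.27, and LEFTY1, a secreted antagonist of Nodal, fell by 3.19. GNG2, a G protein subunit, fell by 2.99 and HIC1, a transcriptional repressor, fell by 2.89. CCL2, a chemokine, fell by 2.88, TRIL by 2.67, PCDH18, a protocadherin, by 2.67, TMEM119 by 2.62, SCN7A, a sodium channel, by 2.47 and IFITM1, an interferon-induced membrane protein, by 2.32.

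Marker lists of other cell types were not called. Smooth muscle, neuronal, lymphoid and fat, bone and cartilage lists had camera adjusted p of 0.811, 0.851, 0.468 and 0.851. Single members did change: DCX, a microtubule protein of young neurons, rose by 2.80 ± 0.19, L1CAM fell by 1.87, SYNPO2 rose by 1.81 and RAG1, at a low level of 3.98 in controls, rose by 0.79. The 1 other probe set of L1CAM and that of RAG1 were not called. COL2A1 fell by 1.31. CD36 rose by 2.96 on its brightest probe set, 2 of its 4 other probe sets, 1 shared and 1 not, rose by 0.96 and 0.91, and the others, at low levels, were not called. The brightest unshared one was among those not called, at 0.07 (limma adjusted p = 0.512), so the unshared one that rose was dimmer still. The stress list was not called (adjusted p = 0.458), with log2 changes of 1.40 for HMOX1 and -1.17 for PHGDH. Of 13 housekeeping genes, 3 fell, GUSB by 0.73, HPRT1 by 0.49 and TBP by 0.45, and the list was not called (adjusted p = 0.382). With an intensity trend 7 of them were lower and 2 higher. The 1 other probe set of GUSB and that of HPRT1 were not called. The 3' to 5' difference of the ACTB control probe sets, a sign of RNA quality, was 0.13 in control and 0.178 in MyoD-E arrays (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows), and that of GAPDH was 0.0593 and 0.045 (exact permutation p = 0.5).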

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

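Centring on the spike-ins, on the mean and on the median of the housekeeping genes, and leaving out updated symbols, were chosen after seeing the data, and the mean version was chosen after the shift of the median version had been seen. Without 1 array in turn, called probe sets ranged from 12240 to 13712 (5237 to 5800 higher, 7003 to 7912 lower, 1384 to 1467 and 504 to 667 with a 2-fold change), called genes from 5461 to 6096 (2341 to 2605 higher, 3120 to 3491 lower, 686 to 719 and 255 to 329 with a 2-fold change) and lists from 9 to 11 (5 to 6 higher, 4 to 6 lower). Tested against a fold of 1.5, 2175 probe sets passed, 1514 higher and 661 lower, a stricter question by construction. With an estimated correlation 0 of the 10 lists passed, 0 higher and 0 lower, and without updated symbols 1 did, the sarcomere list. That form of camera also uses fewer degrees of freedom, so the loss cannot be put down to correlation alone. Centred on the housekeeping mean, 11760 probe sets were higher and 5298 lower (380 lower by 2-fold), and 4801 genes were higher and 2489 lower. Centred on their median, 3033 probe sets were higher and 18220 lower (1341 by 2-fold), and 1387 genes were higher and 6851 lower (654 by 2-fold). These shifts of 0.13 and -0.23 come from the construction of the centring. The housekeeping median rose with MyoD-E although the median log2 fold change of its genes was -0.0863, so that version does not follow them. Centring on the housekeeping median also changed the error: each named gene whose call moved had the same standard error, 0.141. Calls lost or gained in that setting therefore cannot be put down to the shift alone. Without shared probe sets MYCN read 0.0467, RBPJ -0.126, COL1A2 -0.061 and ACAN 0.122; the cause was not tested. With the housekeeping median SPARC read -0.003, by the same shift of -0.23. The replicate number as a block gave 14643 probe sets, 6405 genes and 10 lists, and ended 2 of the 148 calls among the named genes, SPARC (adjusted p = 0.0591) and EBF1 (0.0558). The labels do not say whether the numbers pair the arrays. Same-number residual correlations were 0.023 to 0.0826, and 5 of 6 arrays correlated best with their own number, a hint of pairing from the data only. The other totals of probe sets, genes and lists stayed within 1.5 times, but counts within lists did not: in 22 of 26 lists some setting moved the higher or the lower count by more, in 11 lists with each housekeeping centring and in 17 without shared probe sets, where fewer genes are measured. Dim probe sets have signal close to background, which limits folds from low levels. The alternative for linear values was not run, as the values are on a log scale.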

Other observations

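The genes of this paragraph were chosen after their values were seen. They are single genes, not a tested group. TEX14, which acts in germ cell division, rose by 5.09 ± 0.16 (log2 fold change ± SE), FATE1, a testis gene, by 4.99 ± 0.15 and TDRD1, a germline tudor protein, by 3.05 ± 0.14. The small heat shock genes HSPB7 and HSPB8 rose by 4.68 and 2.58, and the muscle ubiquitin ligase adaptors ASB5 and KLHL40 by 2.68 and 2.55. Log2 changes were -2.22 for SOX4, -2.02 for MEOX1, -1.67 for LGR5, -1.45 for GPC3 and -1.33 for GLI3. MDFI, an inhibitor of MyoD family factors, fell by 1.27 ± 0.15. The sterol exporters ABCA1 fell by 1.87 ± 0.42 and ABCG1 fell by 1.77 ± 0.43, and their regulator NR1H3 fell by 1.45 ± 0.13, although the MyoD-E arrays spread widely for both exporters.

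The tests on the interferon genes, on the excess of lower calls and on S phase were chosen only after the result was seen. The test on all other splits of the arrays was planned. With 10 splits of 6 arrays, no share under 0.05 is possible. The real split called 15011 probe sets and 6608 genes, and the highest other split 0 of each, and 1 of the 10 splits, the real one, gave as many. Each other split has arrays of both groups on each side, so the group difference adds to its residual spread. Its 0 calls are therefore no measure of how many calls unchanged arrays would give. For gene lists the real split called 10 and the highest other split 9. Camera with a preset correlation therefore called nearly as many lists in groupings that mix the groups, and each of those groupings keeps part of the difference between them.

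Several histone genes stood out among the increases while replication genes fell: H3C6 rose by 3.98 ± 0.14, H2BC21 by 3.23 and H2BC4 by 2.75. The control levels of H3C6 and H2BC4, 4.55 and 5.02, lay below the array medians, and H2BC21 was read by a shared probe set. Over all 45 measured histone genes, a set that also holds linker genes used outside S phase, members went both ways: 15 were higher, 10 lower and the median was 0.012. The set did not pass against other genes (camera p = 0.06, and p = 0.408 with an estimated correlation), while fry found a balance toward higher levels (p = 0.00165, and 0.00192 over the 35 genes with an unshared probe set). The fall of the replication list (median -0.65) prompted the pattern, so it is not a separate test of whether more cells were in S phase. Still, 36 of 41 replication genes were lower and 1 higher, and 39 of 40 genes of G2 and mitosis were lower and 1 higher. For the genes of these lists the levels argue against more cells in S phase, while the share of cells in S phase was not measured. With a family median so near 0, tests for shared probe sets (median 0.012 on unshared ones) and for 1 array (lowest median -0.013 without 1 array) decide nothing. No biological explanation was tested.

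Interferon response genes fell while USP18 rose, although the list's call was lost with an estimated correlation (camera adjusted p = 0.347). Signal at background does not account for it, since the 22 brighter members had a median of -0.63. An offset in array scaling does not either, as the median stayed at -0.29 after the centring that raised it most. The rise of USP18 by 3.45 is part of the pattern, so it does not test a lower interferon signal on the listed genes, which stays open. No biological explanation was tested.

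More genes were called lower than higher. Dim probe sets do not account for it, since without them lower calls were 1.47 times the higher ones. An offset in scaling stays open: the ratio was 0.518 with the housekeeping mean, 4.94 with the housekeeping median and 1.24 with the spike-ins. The ratio of 4.94 carries little weight, since that median rose while the median log2 fold change of its genes was -0.0863. The housekeeping genes were also lower in fry (adjusted p = 0.00288), so they may not be a stable reference. The housekeeping mean and the spike-ins still disagree, so the direction of the excess cannot be told apart from the choice of scaling.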
